A study of Homo sapiens with 36 samples.

How the data were processed

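Per the submitters' processing notes, reads were aligned to hg38 with STAR 2.7.3a, new transcripts were assembled with Cufflinks 2.2.1, and reads were counted per gene with featureCounts 2.0.0. The deposited values were raw integer counts per gene, which the authors had not normalised. Libraries had been made with a stranded total RNA kit after depletion of ribosomal RNA and sequenced on a NovaSeq instrument. Each of the 36 deposited tables held 58682 features, 58174 with Ensembl identifiers and 508 assembled loci without coordinates. Of the identifiers 57836 matched GENCODE release 29, from which symbols, classes and coordinates were taken, and 55008 had the same version. The annotation release, the strand setting and the handling of overlapping genes were not stated. Among genes nested within another on the same strand, the host had at least the count of the nested gene in 990 of 1004 pairs (98.6%), against 170 of 507 (33.5%) on opposite strands. Counts had therefore been made by strand and gone to each overlapping gene of a strand, and values of genes that overlap on one strand are uncertain.

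Groups followed the sample titles. One library in each fraction, replicate 3 of clone1 without induction, was titled clone1 and described as clone2, and was kept in clone1. Its lowest correlation with clone1 was 0.9981 in the cytoplasm and 0.9975 in chromatin, and its best with another group 0.9936 and 0.9937 (Pearson r, log2 CPM). Over all libraries the lowest correlations within a group were 0.9961 and 0.9966 and the highest between groups 0.9942 and 0.9951, and each of the 36 libraries was closer to its own group. Within groups the counts of genes with at least 20 counts varied by a chi-square of 1.66 to 21.62 per degree of freedom between libraries, where resequencing one library would give a value near 1. Libraries of one replicate number did not vary together across groups, with a median r of their deviations of −0.004 in the cytoplasm (range −0.412 to 0.315) and 0.018 in chromatin (range −0.259 to 0.341). The numbers were therefore not used as pairs.

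Analyses ran in R 4.3.3. Genes were kept with the filter of edgeR 4.0.16, libraries scaled by the trimmed mean of M values (TMM), and quasi-likelihood F tests fitted per fraction with 1 mean per group. Contrasts were the response to induction of each line, the net response (mean of the clones' responses minus that of the control), the difference between the clones' responses, and each clone minus the control before induction (baseline). A fit over all libraries gave the difference of the net response between fractions and the cytoplasm minus chromatin difference in the control line (fractionation). Genes were called at a Benjamini-Hochberg adjusted p under 0.05. A gene called in both clones was called in each clone and in the net response, with one direction. CPM are counts scaled to a common library total. The comparisons, groups, gene lists, alternatives and thresholds were set before the data were examined, except where the text says otherwise.

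The 30 gene lists were decapping and P-body factors, deadenylation factors, the RNA exosome and SKI complex, XRN and other 5′ exonucleases, NMD factors, protein-coding NMD substrates, snoRNA host genes, small nucleolar and Cajal body RNAs, immediate-early and AU-rich-element mRNAs, interferon-stimulated genes, ATF4 targets, p53 targets, aryl hydrocarbon receptor targets, mitochondrially encoded mRNAs, mitochondrial chaperones and proteases, S-phase genes, G2 and mitosis genes, histone genes, ribosomal protein genes, translation factors, chaperones, cholesterol synthesis, glycolysis and hypoxia, ZNF genes, nuclear RNAs, cytoplasmic marker mRNAs, and epithelial, fibroblast, endothelial and leukocyte markers. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and a prior count of 2, adjusted over the lists of a contrast. Camera with an estimated correlation and the rotation test fry were run as alternatives. Counts of members are given as called among all genes and, in parentheses, with the adjustment repeated over the list alone.

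Genes were named by rule. XRN1 was reported in every group. For responses in both clones the rule took the 10 largest rises and falls by the smaller of the 2 clones' log2 fold changes, among genes with a symbol, a mean of at least 1 CPM over the 18 libraries, and all 3 induced libraries beyond all 3 not induced ones in each clone, and the text names part of these. The control response, the baselines and the fraction difference each contributed 5 rises and 5 falls, and each list that passed contributed the 4 members with the smallest adjusted p. The text names part of these as well, and 1 withheld result is not reported. For fractionation the 4 most abundant members of the nuclear and the cytoplasmic list were taken, and for other cell types the most abundant marker. Outside this rule, the following were chosen after their values were seen: the fraction differences of SNHG1, EPB41L4A-AS1, PEAR1, CLK1, ZNF276 and MT-CO2, the cytoplasmic net change of TERT, the baseline of CDH1, and SERBP1, C1orf141 and AL389925.1 beside IL23R. So were the named members of the lists added in the closing section.

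The procedure was tested on simulated data with 200 changed genes at 1.5, 2 and 4 times. The net response recovered 80.6%, 97% and 100% of them in the cytoplasm and 86.6%, 100% and 100% in chromatin, with 8 and 11 false calls among 19375 and 24831 genes. The clone1 response had 19 and 10 false calls, the clone2 response 8 and 15, and the response in both clones 0 and 0. The list test found 1 of 1 changed list in each fraction. The 30 genes of that list were all raised and genes were drawn independently, so this does not test lists of correlated genes. Variation between cultures was not simulated.

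The overlap of the clones' baselines, which share the control libraries, was compared with 10 simulations of unchanged clones. In each, control libraries were simulated as well and shared by both clones. Alternatives included the scaling of relative log expression (RLE), library totals alone, DESeq2 1.42.0, other filters, the omission of each library in turn, libraries summed per line and treatment, the replicate number as a block and the clone2 assignment of the library with conflicting labels. A further one, chosen later, dropped genes that overlap a same-strand gene with at least 20% of their own total count, and genes without coordinates.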

Results

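Total RNA depleted of ribosomal RNA was sequenced from derivatives of HCT116, a human colorectal carcinoma line, after separation of the cells into a cytoplasmic and a chromatin fraction. XRN1 is the main cytoplasmic exonuclease that degrades decapped RNA from its 5′ end. In each of 2 clones, named clone1 and clone2, the XRN1 gene had been edited to carry an auxin-inducible degron, a tag that lets the plant protein TIR1 mark a protein for destruction when auxin is present. The control line carried doxycycline-inducible TIR1 without the tag. Each of the 3 lines was sampled without induction and after 24 h with doxycycline (2 µg/ml) and auxin (500 µM), which gave 12 groups of 3 libraries over both fractions. The 3 libraries of a group were described as technical replicates, so the p-values below measure the spread between libraries and not between cultures. Counts summed to 31.2 M to 49.3 M per cytoplasmic library and 44.3 M to 62.7 M per chromatin library, with 26432 to 28464 and 32116 to 33425 genes detected. The 10 most abundant genes took 16.79% to 22.74% of the cytoplasmic counts and 3.91% to 8.27% of the chromatin counts.

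XRN1 mRNA (ENSG00000114127.10, GRCh38 chromosome 3, 142306607 to 142448062, minus strand) was lower in the cytoplasm of both tagged clones before any induction. Its cytoplasmic level was 63.4 ± 3.06 CPM (counts scaled to a common library total; SD, n = 3) in the control line, 21.8 ± 0.204 in clone1 and 21.6 ± 0.299 in clone2. These differences were −1.54 (SE 0.04) and −1.55 (SE 0.04) on the log2 scale, with adjusted p = 6.13e-18 and 2.91e-17 (edgeR, Benjamini-Hochberg). Chromatin levels lay much closer together, at 113 ± 0.367 CPM in the control, 103 ± 2.82 in clone1 and 108 ± 2.54 in clone2 (SD, n = 3), and log2 differences of −0.13 (adjusted p = 0.00537) and −0.06 (adjusted p = 0.218, edgeR with Benjamini-Hochberg). Induction raised XRN1 mRNA in all 3 lines. The cytoplasmic mean went to 75.9 ± 2.7 CPM in the control, 29.1 ± 0.788 in clone1 and 28.6 ± 0.648 in clone2, and the chromatin mean to 141 ± 3.8, 131 ± 4.09 and 136 ± 0.779 (SD, n = 3). The degron acts on the XRN1 protein, which was not measured here, so these mRNA values do not check the depletion. The gene had been edited in the clones while reads were aligned to the reference genome, and how the edit affects its counts was not tested.

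**Figure D1:**
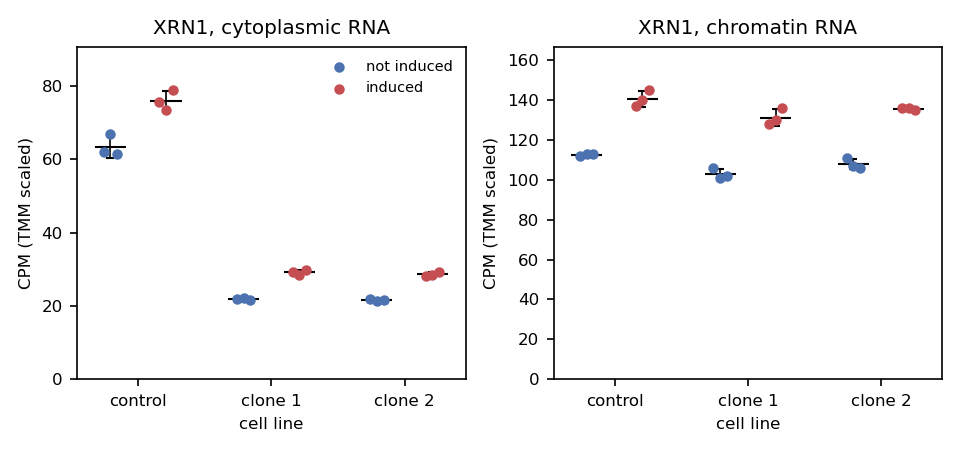
XRN1 CPM in each library of the cytoplasmic and chromatin fractions, by line and induction, with the group mean and SD (n = 3). Both clones lie near 22 to 29 CPM in the cytoplasm, below the control at 63.4 and 75.9 CPM, while all lines lie between 103 and 141 CPM in chromatin.

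Known markers followed the fraction labels. In the control line without induction, EEF1A1, a translation elongation factor, was higher in the cytoplasm by 5.99 (log2, SE 0.10), the ribosomal protein RPLP0 by 5.97 (SE 0.07), and the glycolytic enzymes GAPDH by 5.69 (SE 0.08) and ENO1 by 4.03 (SE 0.06). The nuclear long noncoding RNAs NEAT1, FTX, PVT1 and MALAT1 were lower in the cytoplasm, with log2 differences of −4.28 (SE 0.07), −4.03 (SE 0.08), −3.40 (SE 0.07) and −1.98 (SE 0.08). Of 25282 genes tested over both fractions, 9593 were higher and 12879 lower in the cytoplasm at an adjusted p under 0.05 (edgeR, Benjamini-Hochberg), and with library totals alone as the scaling the split was 6338 and 16938 and the median of all genes −1.414 against −0.471. Each library is scaled to itself, so these are relative abundances.

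The first question was which cytoplasmic RNAs changed in both clones beyond the response of the untagged line. PEAR1 (ENSG00000187800.13, chromosome 1, 156893698 to 156916434), a platelet and endothelial receptor, rose from 3.96 ± 0.0331 to 17 ± 1.06 CPM in clone1 and from 3.76 ± 0.0825 to 13.9 ± 0.569 in clone2, against 2.74 ± 0.472 and 3.14 ± 0.634 in the control (SD, n = 3). GBP3, an interferon-inducible GTPase, rose by 2.52 (SE 0.20) and 1.76 (SE 0.17), the aspartic protease gene NAPSA by 1.86 (SE 0.21) and 2.24 (SE 0.23), and the butyrophilin pseudogene BTN2A3P by 1.93 (SE 0.10) and 1.71 (SE 0.10) on the log2 scale in clone1 and clone2. None of these 4 passed the test in the control line, where their log2 differences were 0.18, 0.60, 0.11 and 0.29, and the change in the clones exceeded that in the control by 1.81 (SE 0.15), 1.54 (SE 0.30), 1.95 (SE 0.40) and 1.53 (SE 0.17). Among the falls were ISPD, needed for dystroglycan glycosylation, at −1.79 (SE 0.10) and −1.62 (SE 0.09), ZBED2, a zinc finger gene, at −1.46 (SE 0.08) and −1.16 (SE 0.07), and the long intergenic RNA AC009502.1 at −1.08 (SE 0.07) and −1.37 (SE 0.07). These falls are the clones' own changes, without the control's change subtracted, though each gene also passed as a fall in the net response. In each clone the 3 induced libraries of each of these genes lay beyond the 3 not induced ones. IL23R, an interleukin 23 receptor subunit with no counts in clone1 before induction, came out at least 81.1-fold higher there, against a floor of 3 counts per library. It also rose in the control line, from 0.0378 ± 0.0329 to 4.02 ± 0.524 CPM (SD, n = 3). Its net call rested on few counts. It ended without either of control replicates 2 and 3, any clone1 library, clone2 replicates 1 and 2, or induced clone2 replicate 2, and with no filter on low counts.

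Across the 19375 genes tested in the cytoplasm, 5801 rose and 4867 fell in clone1, 5671 rose and 4462 fell in clone2, and 4309 rose and 4548 fell in the control line (edgeR, adjusted p under 0.05). The clones shared no library, and 4543 genes rose in both where independent lists would share 1697.9, while 3554 fell in both against 1120.9 and 44 went opposite ways. Both clones received doxycycline and auxin, as did the untagged line, so these overlaps do not measure XRN1 depletion alone. The net response, the mean of the 2 clones' changes minus that of the control, was positive in 3474 genes and negative in 2459. Called in clone1, in clone2 and in the net response with one direction were 2091 rises and 1030 falls, of which 219 and 23 changed at least 2 times in both clones. With library totals alone the median of all genes was 0.246 in clone1, 0.202 in clone2 and 0.162 in the control, against 0.031, 0.027 and 0.005. Library totals gave higher shares of rises, with 81.6% against 54.4% in clone1, 81.4% against 56.0% in clone2, 75.6% against 48.7% in the control, 70.4% against 58.6% in the net response and 88.8% against 67.0% in both clones. Other alternatives lowered the last 2 shares, to 52.3% and 59.8% with relative log expression factors and 53% and 59.6% with DESeq2. Without induced control replicate 1 of the cytoplasm they were 50% and 56.8%, and without any 1 of the 6 induced clone libraries 50.4% to 50.8% and 58.2% to 59.7%. With the 3 libraries of each line and treatment summed, so that the clones were the only replicates, 1577 net calls were made, 1284 higher and 293 lower, against 5933.

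Messenger RNAs known as targets of nonsense-mediated decay (NMD), the pathway that degrades transcripts with a premature stop codon, were higher in the cytoplasmic net response. Of 24 tested members 19 were higher, also when adjusted over the list alone, and 14 rose in both clones, with a median net log2 change of 0.50. The list's median response was 0.168 in clone1 and 0.198 in clone2, against −0.308 in the control, so the control's fall enters the net rise. Against the induced control, the median was 0.51 in induced clone1 and 0.588 in induced clone2. CLK1 (ENSG00000013441.15, chromosome 2, 200853009 to 200864744), a kinase of splicing factors, went from 23.5 ± 0.471 to 54.2 ± 0.626 CPM in clone1 and from 29.8 ± 1.27 to 55.2 ± 1.54 in clone2, and stayed at 22.9 ± 1.03 and 23.5 ± 1.61 in the control (SD, n = 3). GADD45A, a growth arrest gene, rose by 0.49 (SE 0.08) and 0.72 (SE 0.08) in the clones and fell by 1.08 (SE 0.09) in the control. UPP1, uridine phosphorylase, had a net change of 2.13 (SE 0.09) with clone changes of 0.02 and −0.10 that did not pass the test, and a control change of −2.17 (SE 0.08). This list passed limma camera with adjusted p = 1.92e-11, and had adjusted p = 0.0582 with an estimated correlation. Of 16 genes for NMD factors, 8 were higher and 1 lower, the same when adjusted over the list alone, and 6 rose in both clones. SMG1, the kinase that phosphorylates UPF1, rose from 174 ± 3.07 to 290 ± 5.58 CPM in clone1 and from 209 ± 13 to 312 ± 6.63 in clone2 (SD, n = 3), with net changes of 0.79 (SE 0.06) for SMG1, 0.68 (SE 0.06) for SMG9 and 0.44 (SE 0.07) for UPF1. That list had camera adjusted p = 0.0401, and adjusted p = 0.322 with an estimated correlation.

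Host genes of small nucleolar RNAs (snoRNAs), whose spliced exons are short-lived cytoplasmic RNAs, divided. The snoRNAs lie within their hosts on the same strand, and counts had gone to each overlapping gene. Host values can therefore include snoRNA reads, to an extent that was not tested. Of 25 tested members 14 were higher and 3 lower (14 and 5 when adjusted over the list alone), and 9 rose and 3 fell in both clones. EPB41L4A-AS1 (ENSG00000224032.6, chromosome 5, 112160526 to 112164276) rose by 0.69 (SE 0.07) and 0.67 (SE 0.07) in the clones and fell by 1.16 (SE 0.08) in the control, a net change of 1.83 (SE 0.09, edgeR adjusted p = 1.3e-12, Benjamini-Hochberg). C6orf48, SNHG5 and SNHG1 had net changes of 1.49 (SE 0.07), 1.34 (SE 0.08) and 1.18 (SE 0.07), and each fell in the control by 0.80 or 0.81. Against the induced control, the median of the list was 0.046 in induced clone1 and 0.363 in induced clone2. The list had camera adjusted p = 8.94e-05, and adjusted p = 0.336 with an estimated correlation.

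**Figure D2:**
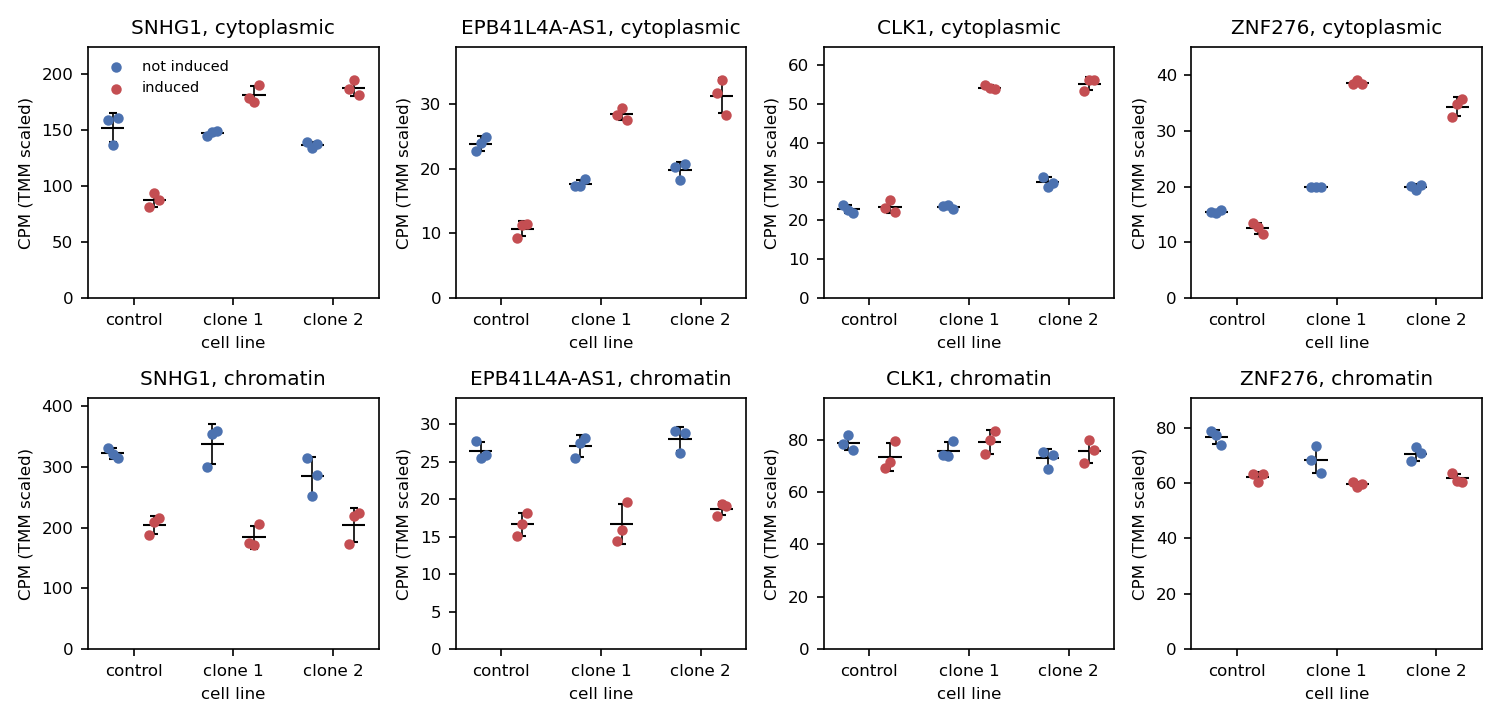
CPM of SNHG1, EPB41L4A-AS1, CLK1 and ZNF276 in each library of both fractions, by line and induction, with the group mean and SD (n = 3). Cytoplasmic CLK1 doubles or nearly so in the induced clones, from 23.5 to 54.2 and from 29.8 to 55.2 CPM, and stays at 22.9 and 23.5 CPM in the control.

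Targets of ATF4, the transcription factor of the integrated stress response, had the largest net median of any list that passed, at 0.94 log2. In the cytoplasm 27 of 28 were higher, also when adjusted over the list alone, but only 9 rose in both clones, and 26 of the 28 fell in the control line. DDIT3, which encodes the stress factor CHOP, rose from 24.8 ± 1.96 to 62.4 ± 2.31 CPM in clone1 and from 18.5 ± 4.51 to 49.1 ± 3.13 in clone2, and fell from 33.3 ± 2.99 to 18.9 ± 2.47 in the control (SD, n = 3). XPOT, a tRNA exporter, had a net change of 0.73 (SE 0.05) that combined 0.02 (not called) and 0.13 in the clones with −0.65 in the control. SESN2, a stress-induced sestrin, had 1.78 (SE 0.12), and SLC1A5, a glutamine transporter, 0.64 (SE 0.05). The list had camera adjusted p = 6.28e-18, and adjusted p = 0.106 with an estimated correlation. Immediate-early mRNAs and others with AU-rich elements, which are short-lived, were higher in 18 of 40 (21 when adjusted over the list alone), 13 of them in both clones, among them the transcription factors KLF4 with a net change of 1.31 (SE 0.12) and KLF6 with 0.90 (SE 0.11) and the growth factor VEGFA with 0.98 (SE 0.08). That list had camera adjusted p = 2.36e-05, and adjusted p = 0.366 with an estimated correlation. Zinc finger genes with ZNF symbols were higher in 109 and lower in 20 of 406 (111 and 20 when adjusted over the list alone), with 73 rises in both clones, and ZNF276 had 1.18 (SE 0.07), ZNF286B 0.90 (SE 0.07), ZNF473 0.83 (SE 0.06) and ZNF335 0.83 (SE 0.07). Their camera adjusted p was 0.000217, with adjusted p = 0.0582 with an estimated correlation.

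Part of the histone, S-phase, mitotic and chaperone genes were lower in the net response of the cytoplasm. Replication-dependent histone genes were lower in 36 and higher in 4 of 58 (40 and 5 when adjusted over the list alone), with 35 falls in both clones. HIST1H2BN and HIST2H2AB each had −0.42 (SE 0.08), while the low genes HIST1H3C and HIST1H1T had 1.59 (SE 0.22) and 1.16 (SE 0.20). Against the induced control, the histone median was −0.054 in induced clone1 and −0.073 in induced clone2, as both clones started higher. The histone list had camera adjusted p = 8.57e-06, and adjusted p = 0.433 with an estimated correlation. S-phase genes were lower in 12 and higher in 1 of 23 (13 and 1 when adjusted over the list alone), with −0.38 (SE 0.05) for MCM4 and −0.32 (SE 0.04) for MCM6, subunits of the replicative helicase. Their camera adjusted p was 0.000281, or adjusted p = 0.322 with an estimated correlation. Genes of G2 and mitosis were lower in 8 and higher in 1 of 23 (9 and 2 when adjusted over the list alone), with −0.31 (SE 0.05) for the anaphase activator CDC20. Their camera adjusted p was 0.000739, or adjusted p = 0.322 with an estimated correlation. Chaperone genes were lower in 10 of 13 (11 when adjusted over the list alone), with −0.51 (SE 0.06) for HSP90AA1 and −0.41 (SE 0.05) for HSP90AB1. The chaperone list had camera adjusted p = 8.57e-06, or adjusted p = 0.102 with an estimated correlation.

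Mitochondrially encoded mRNAs were lower in 12 of 13, also when adjusted over the list alone, 5 of them in both clones, with a median of −0.74. Before induction their median difference from the control was −0.051 in clone1 and 0.645 in clone2. Against the induced control it was −0.74 in induced clone1, with 12 lower and 0 higher. In induced clone2 it was −0.249, with 1 lower and 2 higher. MT-CO2 and MT-CO1, subunits of cytochrome oxidase, had −0.55 (SE 0.10) and −0.48 (SE 0.09). The list had camera adjusted p = 1.87e-05, and adjusted p = 0.322 with an estimated correlation. The share of all cytoplasmic counts on the mitochondrial genome went from 0.437% ± 0.051 to 0.376% ± 0.016 in clone1 and from 0.663% ± 0.109 to 0.483% ± 0.012 in clone2, and from 0.433% ± 0.087 to 0.521% ± 0.098 in the control (SD, n = 3). Cholesterol synthesis genes were lower in 12 of 24, also when adjusted over the list alone, with −0.44 (SE 0.06) for squalene synthase FDFT1 and −0.49 (SE 0.07) for lanosterol synthase LSS. They had camera adjusted p = 2.36e-05, or adjusted p = 0.322 with an estimated correlation. Glycolysis and hypoxia genes were lower in 14 and higher in 2 of 23 (15 and 3 when adjusted over the list alone), with −0.40 (SE 0.05) for lactate dehydrogenase LDHA. The list had camera adjusted p = 0.000294, or adjusted p = 0.322 with an estimated correlation.

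Abundant cytoplasmic marker mRNAs were lower in 9 of 14, also when adjusted over the list alone, with −0.30 (SE 0.06) for PPIA, a peptidyl-prolyl isomerase, and −0.36 (SE 0.06) for TUBB, a tubulin. The markers had camera adjusted p = 9.63e-05, or adjusted p = 0.322 with an estimated correlation. Smaller shifts were found for cytosolic ribosomal protein genes, lower in 7 of 79 (2 when adjusted over the list alone; camera adjusted p = 0.000739; adjusted p = 0.668 with an estimated correlation). Translation factors were lower in 6 and higher in 2 of 32, the same when adjusted over the list alone, with −0.63 (SE 0.14) for the poly(A)-binding protein PABPC1. The factors had camera adjusted p = 0.0144, or adjusted p = 0.567 with an estimated correlation. The snoRNAs themselves were lower in 11 and higher in 4 of 213 (1 and 1 when adjusted over the list alone; camera adjusted p = 0.0178; adjusted p = 0.489 with an estimated correlation). With the libraries of each line and treatment summed, the calls ended for HSP90AA1, HSP90AB1, MCM4, MCM6, CDC20, MT-CO1, LDHA, TUBB and PPIA.

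**Figure D3:**
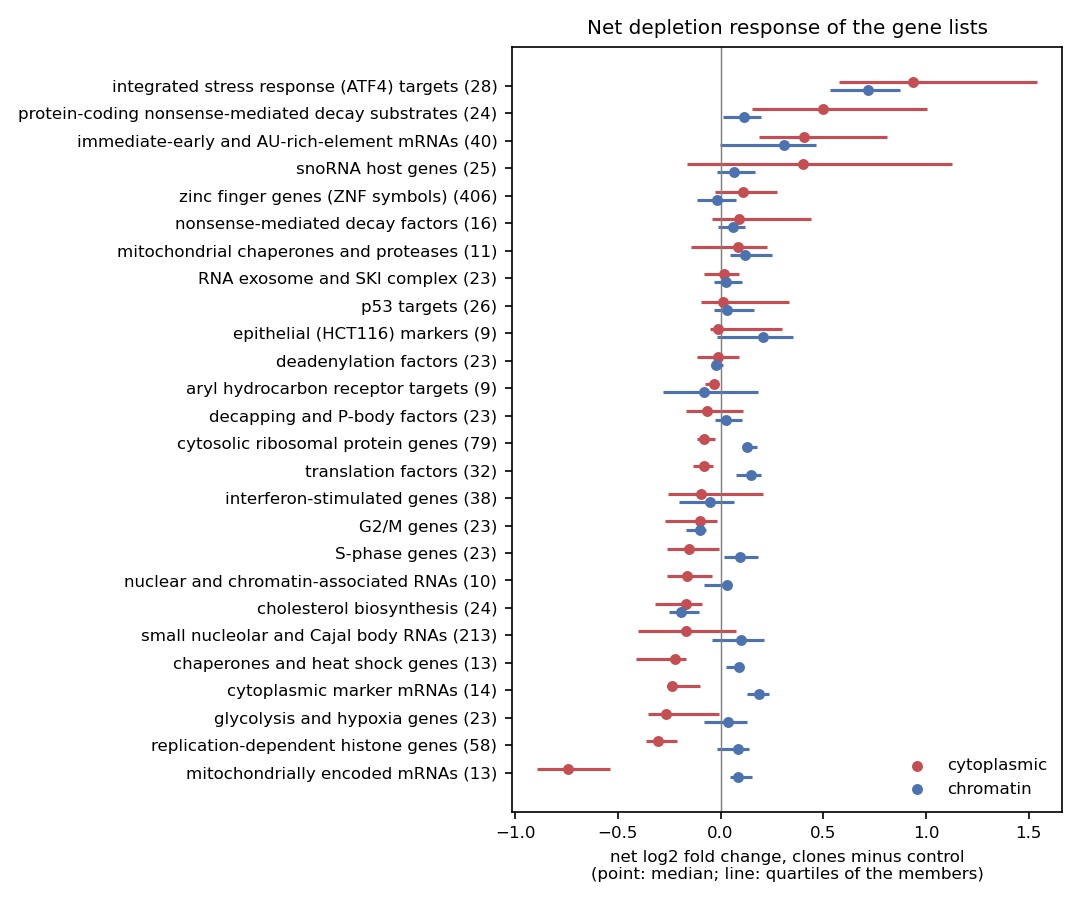
Net log2 fold change of gene lists in the cytoplasm and in chromatin (points, medians; lines, quartiles; numbers in parentheses, members tested in the cytoplasm). The ATF4 target list has the highest median in both fractions, at 0.94 and 0.72, and mitochondrially encoded mRNAs the lowest cytoplasmic one, at −0.74.

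Lists of other RNA decay and signalling genes did not pass in the cytoplasm. Decapping and P-body factors had 6 higher and 3 lower of 23 (limma camera adjusted p = 0.625), deadenylation factors 3 and 4 of 23 (adjusted p = 0.723), the RNA exosome and SKI complex 4 and 3 of 23 (adjusted p = 0.723). By the same limma camera test, p53 targets had 10 and 1 of 26 (adjusted p = 0.204), aryl hydrocarbon receptor targets 1 and 1 of 9 (adjusted p = 0.682), mitochondrial chaperones and proteases 4 and 3 of 11 (adjusted p = 0.426), and nuclear RNAs 2 and 5 of 10 (adjusted p = 0.204). These counts were the same when adjusted over the list alone. Interferon-stimulated genes had 8 higher and 11 lower of 38 (9 and 13 when adjusted over the list alone; adjusted p = 0.268) and epithelial markers 3 and 1 of 9 (3 and 2 when adjusted over the list alone; limma camera adjusted p = 0.766). For the deadenylation, interferon, aryl hydrocarbon receptor and epithelial lists the median was negative and the mean positive. Markers of other cell types were scarce. The most abundant were COL1A1 for fibroblasts at 3.69 CPM in the cytoplasm and 17.9 in chromatin, VWF for endothelium at 0.761 and 2.28, and the leukocyte markers CORO1A at 3.56 in the cytoplasm and CD68 at 1.38 in chromatin, against 808 and 119 CPM for the epithelial keratin KRT8. In chromatin the fibroblast and endothelial lists did not pass (limma camera adjusted p = 0.645 and 0.638). Too few members were tested for the leukocyte list and for the 5′ exonucleases, where XRN2, the nuclear relative of XRN1, averaged 189 CPM in the cytoplasm and 210 in chromatin.

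Among annotated gene classes, unprocessed and transcribed pseudogenes were higher in the cytoplasmic net response. Of 629 tested, 162 were higher and 16 lower, 127 rose and 3 fell in both clones, and 37 rose at least 2 times. This class passed camera with adjusted p = 0.00183, and adjusted p = 0.00271 with an estimated correlation. Assembled loci without an annotated gene were higher in 75 and lower in 15 of 444 (camera adjusted p = 0.0351; adjusted p = 0.406 with an estimated correlation), and they have no coordinates here. They fell in each line, 255 of them in the control (median −0.739), 231 in clone1 (−0.517) and 168 in clone2 (−0.333), so the net rise reflects the larger fall in the control, and only 10 rose and 12 fell in both clones. Processed pseudogenes, copies made by retrotransposition, had 24 higher and 10 lower of 453 (limma camera adjusted p = 0.298). Pseudogene counts are uncertain where reads match the parent gene.

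In chromatin, fewer genes changed. Of 24831 tested, the net response was positive in 1382 and negative in 1551, and 381 rose and 327 fell in both clones, 9 and 11 of them at least 2 times (edgeR, Benjamini-Hochberg adjusted p under 0.05). CREB5, a transcription factor of the CREB family, rose by 1.34 (SE 0.18) and 1.12 (SE 0.17) in the clones and fell by 0.57 (SE 0.17) in the control. IL31RA, an interleukin 31 receptor subunit, rose by 1.12 (SE 0.11) and 0.92 (SE 0.11) and fell by 0.53 (SE 0.11) in the control. ISPD fell by 1.75 (SE 0.05) and 1.54 (SE 0.05), the bone morphogenetic protein BMP4 by 1.16 (SE 0.06) and 0.93 (SE 0.06), the neurotrophin BDNF by 1.20 (SE 0.04) and 1.11 (SE 0.04), and TERT, the catalytic subunit of telomerase, by 1.03 (SE 0.07) and 0.99 (SE 0.07). Chromatin TERT had a net change of −0.38 (SE 0.09) and cytoplasmic TERT one of 0.38 (SE 0.14). Within each clone 5004 genes rose and 5328 fell in clone1 and 4678 rose and 4728 fell in clone2, with 3310 shared rises against 942.7 for independent lists, 3461 shared falls against 1014.5, and 64 opposite calls. These overlaps also include any response to doxycycline and auxin. Library totals alone gave 62.5% rises against 48.4% in clone1. Summing the libraries of each line and treatment left 342 net calls, 274 higher and 68 lower, against 2933, and without clone2 replicate 3 the count in both clones was 1115 against 708. With the not induced clone1 replicate 3, whose labels conflict, counted as clone2, the net count was 1808 and the count in both clones 397.

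ATF4 targets were also higher in chromatin. Of 27 tested, 24 were higher (25 higher and 1 lower when adjusted over the list alone), 4 of them in both clones, with a median of 0.72. PHGDH and PSAT1, enzymes of serine synthesis, had net changes of 0.78 (SE 0.07) and 0.86 (SE 0.08), while the control fell by 0.53 and 0.67. DDIT4, a stress-induced inhibitor of mTORC1, had 1.28 (SE 0.12) with clone changes of −0.07 and 0.20 that did not pass the test. The list had camera adjusted p = 4.83e-27, and adjusted p = 0.105 with an estimated correlation. Cholesterol synthesis genes were lower in 11 of 24 (12 when adjusted over the list alone), with −0.49 (SE 0.08) for INSIG1, a sterol sensor partner. The list had camera adjusted p = 2.26e-07, or adjusted p = 0.105 with an estimated correlation. Immediate-early mRNAs were higher in 12 of 40 (14 when adjusted over the list alone; camera adjusted p = 1.65e-05; adjusted p = 0.629 with an estimated correlation), with 0.55 (SE 0.07) for VEGFA. Translation factors were higher in 9 of 32 (14 when adjusted over the list alone; camera adjusted p = 9.41e-06; adjusted p = 0.64 with an estimated correlation), and ribosomal protein genes in 2 of 79, with a list median of 0.13 (camera adjusted p = 2.26e-07; adjusted p = 0.735 with an estimated correlation).

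Smaller chromatin lists also passed camera. NMD substrates were higher in 4 of 24, also when adjusted over the list alone, with 0.75 (SE 0.11) for the cystine transporter SLC7A11 (list camera adjusted p = 0.00191, adjusted p = 0.64 with an estimated correlation). Their median response was −0.12 in clone1 and −0.148 in clone2, against −0.288 in the control, so the net rise of the list reflects the larger fall in the control. Mitochondrial chaperones were higher in 3 of 11 (4 when adjusted over the list alone), with 0.50 (SE 0.08) for HSPA9 and 0.52 (SE 0.07) for the protease LONP1 (list adjusted p = 0.00587; adjusted p = 0.629 with an estimated correlation). Cytoplasmic marker mRNAs were higher in 3 of 14 (4 when adjusted over the list alone), with 0.24 (SE 0.05) for pyruvate kinase PKM (list adjusted p = 0.0016; adjusted p = 0.64 with an estimated correlation). Epithelial markers were higher in 3 of 9 (6 when adjusted over the list alone; list adjusted p = 0.0239; adjusted p = 0.629 with an estimated correlation). S-phase genes were higher in 2 of 23, with 0.25 (SE 0.06) for MCM5 (list adjusted p = 0.0151; adjusted p = 0.735 with an estimated correlation). Genes of G2 and mitosis were lower in 3 of 23, with −0.25 (SE 0.07) for CENPE (list adjusted p = 0.00638; adjusted p = 0.735 with an estimated correlation). None of the list calls of the net response in either fraction held with an estimated correlation. The pseudogene class that was higher in the cytoplasm had 25 higher and 37 lower of 934 in chromatin (limma camera adjusted p = 0.589).

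The next comparison asked whether a gene's net response differed between the fractions, in one fit over all 36 libraries. For EPB41L4A-AS1 the cytoplasmic net change exceeded the chromatin one by 1.79 (SE 0.14), for SNHG1 by 1.18 (SE 0.14), for PEAR1 by 1.71 (SE 0.16), for CLK1 by 0.83 (SE 0.10) and for ZNF276 by 1.07 (SE 0.09). SNHG1 in chromatin fell by 0.88 (SE 0.09) in clone1, 0.47 (SE 0.09) in clone2 and 0.66 (SE 0.09) in the control. The snoRNA class also fell in chromatin, with medians of −0.568, −0.334 and −0.559, and snoRNA reads may enter the SNHG1 counts. In all, 1873 genes had the higher change in the cytoplasm and 1309 in chromatin (edgeR, Benjamini-Hochberg adjusted p under 0.05). That split depended on the scaling, with 1215 and 2782 by relative log expression factors, 2237 and 696 by library totals alone and 1335 and 3195 by DESeq2, and with relative log expression factors the median of all genes was −0.104 against −0.007. The transcribed pseudogene AC004980.1 had a difference of 2.56 (SE 0.40), and the antisense gene AL021707.6, uncertain because it overlaps AL021707.1 on its own strand, 2.50 (SE 0.52). The antisense gene VLDLR-AS1, at 0.1 to 0.291 CPM in the cytoplasm, had −2.16 (SE 0.57), a call that ended without induced control replicate 3 of the cytoplasm.

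The 2091 genes that rose in both clones in the cytoplasm had a median net change of 0.47 there and of 0.04 in chromatin, with chromatin quartiles of −0.06 and 0.15 over the 2085 tested, of which 321 were called higher and 95 lower there. The 127 pseudogenes among them had medians of 0.93 and 0.01. The 1030 genes that fell had medians of −0.26 and −0.01. These genes were chosen by their cytoplasmic change, which enters the test of the difference, so their calls in that test are not counted here and their cytoplasmic medians are inflated. Among the lists, NMD substrates differed upwards in 15 and downwards in 2 of 24, the same when adjusted over the list alone, snoRNA host genes in 11 and 1 of 25 (11 and 2), ATF4 targets in 9 and 2 of 28 (10 and 3), and ZNF genes in 65 and 5 of 420 (75 and 10 when adjusted over the list alone). Mitochondrially encoded mRNAs differed downwards in 10 of 13 (12 when adjusted over the list alone), with −0.67 (SE 0.18) for MT-CO2. So did 9 of 14 cytoplasmic markers (12 when adjusted over the list alone), 8 of 13 chaperones (10), 11 of 23 S-phase genes (12), 12 of 32 translation factors (17) and 12 of 23 glycolysis and hypoxia genes (13), another 3 of which differed upwards (also 3). Over 18706 genes tested in both fractions the net changes had Pearson r = 0.268 and Spearman rho = 0.238, across genes, which are not independent replicates, and r = 0.344 over the 14153 genes with a mean of at least 1 CPM. Higher in both fractions were 615 genes where independent lists would share 238.4, and lower in both 457 against 193.4.

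The untagged line also changed on induction with doxycycline and auxin. Each group may come from a single culture, so in this line alone the drugs and a difference between cultures cannot be told apart. IL23R rose from 0.0381 ± 0.0199 to 28.4 ± 0.608 CPM and IL12RB2, the gene of an interleukin 12 receptor subunit beside it, from 0.0501 ± 0.0105 to 6.55 ± 0.298 CPM in chromatin (SD, n = 3). CEMIP, a hyaluronan-degrading protein, rose by 3.37 (SE 0.15) in the cytoplasm and 3.12 (SE 0.07) in chromatin, and SMPD1, acid sphingomyelinase, by 1.97 (SE 0.16) in the cytoplasm. Falls included the neuropeptide gene SPX at −2.97 (SE 0.23) and LURAP1L at −2.91 (SE 0.27) in the cytoplasm, and the keratin KRT80 at −3.00 (SE 0.34), the hexokinase relative HKDC1 at −2.98 (SE 0.22) and the chloride channel BEST1 at −2.51 (SE 0.29) in chromatin. All 79 ribosomal protein genes fell in both fractions, also when adjusted over the list alone, with medians of −0.36 in the cytoplasm (camera adjusted p = 3.34e-18; adjusted p = 0.289 with an estimated correlation) and −0.61 in chromatin (camera adjusted p = 3.6e-29; adjusted p = 0.233 with an estimated correlation). In the cytoplasm 23 of 25 snoRNA host genes fell (also over the list alone; camera adjusted p = 2.42e-12; adjusted p = 0.114 with an estimated correlation), 26 of 28 ATF4 targets (also over the list alone; camera adjusted p = 5.57e-12; adjusted p = 0.13 with an estimated correlation) and 45 of 58 histone genes (47 over the list alone; camera adjusted p = 4e-10; adjusted p = 0.273 with an estimated correlation). Interferon-stimulated genes rose in 19 of 38 (20 over the list alone; camera adjusted p = 6.48e-06; adjusted p = 0.0561 with an estimated correlation). In total 8857 genes changed in the cytoplasm and 11447 in chromatin, 5633 of the latter upwards and 5814 downwards (edgeR, Benjamini-Hochberg adjusted p under 0.05).

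**Figure D4:**
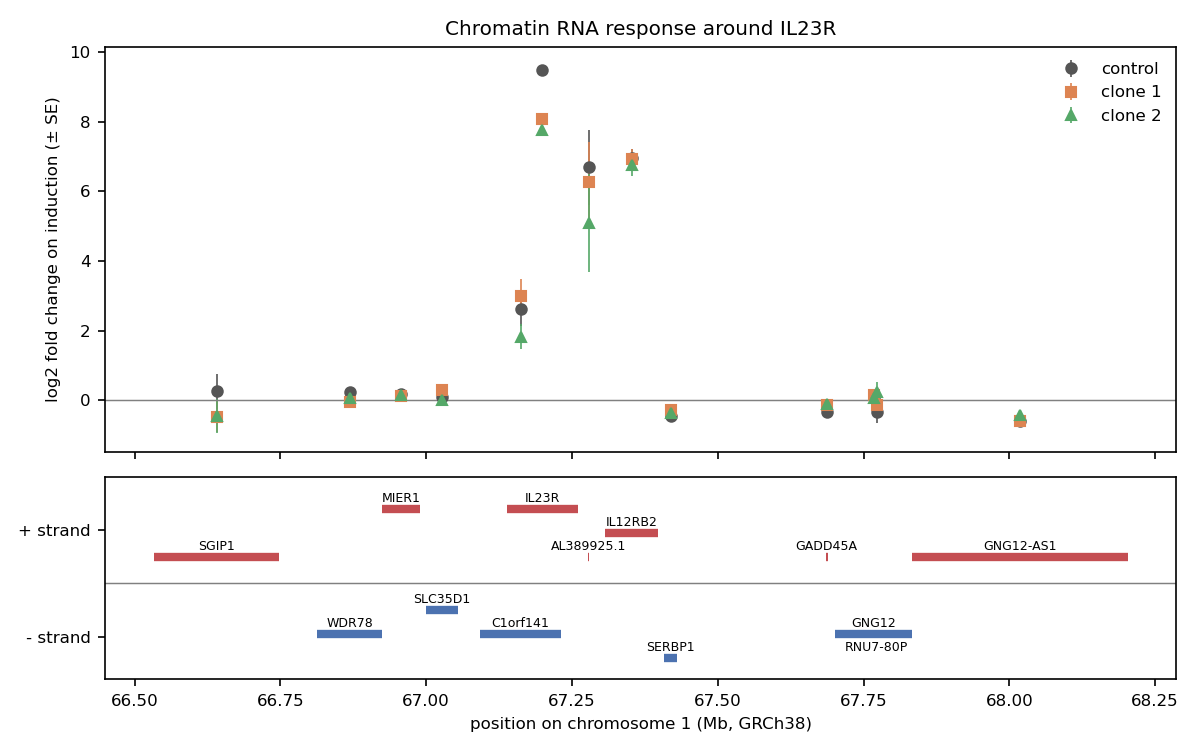
Chromatin log2 fold change on induction (± SE) in the control line, clone1 and clone2 for genes around IL23R on chromosome 1, above a GRCh38 map of the genes by strand. IL23R and IL12RB2, both on the plus strand, rise by 6.76 to 9.47 in every line, while SERBP1, the gene that follows, falls by 0.28 to 0.44.

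Before induction, the clones already differed from the control line. VCAN, the matrix proteoglycan versican, was higher by 2.43 (SE 0.06) in clone1 and 1.66 (SE 0.06) in clone2 in the cytoplasm, and the intermediate filament gene VIM by 1.52 (SE 0.10) and 1.78 (SE 0.10). MYRIP, a linker of secretory granules and myosin, was lower by −3.88 (SE 0.23) and −2.79 (SE 0.20), and LURAP1L by −2.98 (SE 0.26) and −3.01 (SE 0.27). The clones differed from each other in PRKAA2, a catalytic subunit of AMP-activated kinase, at −3.59 (SE 0.19) in clone1 and 1.26 (SE 0.11) in clone2, and in the growth factor FGF9 at −0.89 (SE 0.12) and 1.84 (SE 0.09). In chromatin, the bone morphogenetic protein BMP5 was higher by 2.85 (SE 0.13) and 2.84 (SE 0.13), ADAM28, a metalloprotease, lower by −3.76 (SE 0.23) in clone2, and CDH1, which encodes E-cadherin, was at 39.6 ± 1.91 and 48.3 ± 8.25 CPM in the clones against 86.5 ± 4.02 in the control (SD, n = 3). The pseudogene RPL21P40 was higher by 5.73 (SE 0.19) in clone1, a value that reads shared with other copies of RPL21 would make uncertain. Of the epithelial markers, 6 of 9 were lower in clone1 (also over the list alone; camera adjusted p = 0.00139; adjusted p = 0.0727 with an estimated correlation) and 5 of 9 in clone2 (also over the list alone; camera adjusted p = 0.00062; adjusted p = 0.0536 with an estimated correlation) in the cytoplasm.

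Gene groups that moved with induction in the control were also offset in the clones before it. Both comparisons subtract the same not induced control libraries, so they are not independent, and a deviation of those libraries would shift both the same way. ATF4 targets and ribosomal protein genes were lower in both, while histone genes fell in the control and were higher in the clones. ATF4 targets were lower in 22 and higher in 1 of 28 in clone1 (also over the list alone; camera adjusted p = 5.43e-09; adjusted p = 0.392 with an estimated correlation) and lower in 25 in clone2 (also over the list alone; camera adjusted p = 5.98e-18; adjusted p = 0.22 with an estimated correlation), with medians of −0.42 and −0.69 in the cytoplasm. Ribosomal protein genes were lower in 77 of 79 in each clone (77 and 79 over the list alone; camera adjusted p = 5.87e-17 and 2.15e-19; adjusted p = 0.489 and 0.414 with an estimated correlation), and histone genes higher in 34 of 58 in each (36 over the list alone; camera adjusted p = 3.04e-05 and 2.51e-07; adjusted p = 0.593 and 0.505 with an estimated correlation). In total 3856 genes were higher and 3636 lower in clone1 and 3355 and 3406 in clone2 in the cytoplasm, and 3914 and 3804, and 3126 and 3219, in chromatin (edgeR, Benjamini-Hochberg adjusted p under 0.05). With library totals alone, 71.3% and 74.0% of the cytoplasmic calls were higher, against 51.5% and 49.6%, and in chromatin 61.7% against 50.7% for clone1. In the cytoplasm 2041 genes were higher in both clones, where independent lists would share 667.7, and 2143 were lower in both, against 639.2. Simulated unchanged clones that shared a simulated control had at most 1 such gene in either direction. Unchanged groups give few calls by construction, so this value does not measure the overlap of clones that changed independently. The log2 differences of the clones had r = 0.645 across genes against 0.52 in the simulation, and covariance 0.1223 against 0.0159. The 3 control libraries were too few to divide between the clones, so part of the excess can come from the shared controls.

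The clones responded differently to induction in few genes. Clone2 minus clone1 was called in 405 cytoplasmic genes, 299 higher and 106 lower, and in 637 chromatin genes, 406 and 231 (edgeR, Benjamini-Hochberg adjusted p under 0.05). With clone1 replicate 3, the library with conflicting labels, counted as clone2, 79 and 45 genes were called. The change had the same sign in both clones for 264 of the 405 and 364 of the 637, and in 41 and 61 of the rest both clones were called with opposite signs. The difference reached 2 times in 12 cytoplasmic and 52 chromatin genes. Over all tested genes the clones' changes had Pearson r = 0.788 in the cytoplasm and 0.637 in chromatin, across genes, with any response to doxycycline and auxin included. The split depended on the scaling, with 58.2% higher by library totals against 73.8% in the cytoplasm, and 38.2% by library totals and 45.4% by DESeq2 against 63.7% in chromatin. In the cytoplasm the count was 166 and 245 without clone1 replicates 1 and 2, 201, 153 and 237 without induced clone1 replicates 1, 2 and 3, 198 without clone2 replicate 2, 215, 190 and 216 without induced clone2 replicates 1, 2 and 3, and 657 without control replicate 2. In chromatin it was 342 without clone1 replicate 3, 392 and 361 without induced clone1 replicates 1 and 2, and 299 and 375 without induced clone2 replicates 2 and 3.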

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

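The test of chromatin carry-over by the net response was set before its result was seen, as were the counts over other splits of the libraries, while the tests of carry-over by the clones' own responses and by the ranking in the induced control, the tests of scaling and of overlapping genes, those on ATF4 targets and those on the IL23R locus were chosen only after the results were seen. The clones responded differently to induction in 405 cytoplasmic and 637 chromatin genes by a test of the difference, but in 79 and 45 with the library whose labels conflict counted as clone2. The net response differed between the fractions in 3182 genes by such a test. XRN1 mRNA differed between fractions in its offset before induction, with cytoplasm minus chromatin differences of −1.39 (SE 0.05) in clone1 and −1.48 (SE 0.05) in clone2 on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 1.9e-21 and 4.26e-22).

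A set of 2091 genes, 127 of them pseudogenes, rose in the cytoplasm of both induced clones, and 321 of the 2085 tested in chromatin were called higher there. With the RLE factors 1878 genes rose in both clones, and with library totals alone 3099. The choice among these scalings was therefore not the whole cause of the rises. Each scales a library to itself, so a shift common to most genes was not tested. Of the genes with no same-strand overlapping gene of at least 20% of their own count, 1675 rose in both clones. This argues against such overlaps as the whole cause of the rises, while smaller overlaps were not removed. Rises that also exceeded the chromatin change by the test of the difference numbered 915 with RLE factors against 1275, but were chosen by a change that enters the difference. Over all genes the larger side turned with RLE factors and DESeq2, so scaling stays open as a cause of the difference between fractions. Chromatin RNA in the cytoplasmic libraries of the induced clones cannot be told apart: the 1938 genes most enriched in chromatin had a median net change of −0.132 (quartiles −0.445 and 0.266; 145 rose and 70 fell in both clones, against 317, 340 and 328 rises and 42, 37 and 41 falls in the next 3 groups of 1937 or 1938), but the not induced control enters both ranking and net change. Ranked by the induced control, whose noise would raise the net change, the median was −0.076 (quartiles −0.378 and 0.349), again with an upper quartile above 0, and the clones' own responses, free of this, had medians of 0.152 (quartiles −0.213 and 0.573) and 0.023 (quartiles −0.325 and 0.466). Of the 1938 genes most enriched in chromatin in the control without induction, 901 had a mean of at least 1 CPM in the cytoplasm. The next 3 groups had 1231, 1416 and 1523, so their counts of rises and falls are not directly comparable. Slower cytoplasmic decay without XRN1 and a difference between cultures also stay open, as each group may come from 1 culture.

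ATF4 targets were higher in the net response of both fractions while they fell in the induced control. If the state of the control culture without induction were the whole cause, the induced clones would match the induced control. In chromatin the median target was higher there by 0.231 in clone1 and 0.239 in clone2, with lower quartiles of 0.113 and 0.119. These quartiles are across genes and do not measure the spread between cultures, so the test cannot decide. The median response to induction in chromatin was −0.011 in clone1 and 0.272 in clone2, against −0.611 in the control. In the cytoplasm the medians were 0.301 and 0.253 with lower quartiles of 0.08 and 0.028, and the explanations cannot be told apart because the quartiles reach close to 0. An activated stress response in the depleted clones and a difference between cultures both stay open, and the bounds of this test were set after the values were seen.

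IL23R and IL12RB2, neighbours on one strand, rose on induction in every line including the untagged control. Interferon-stimulated genes rose in the chromatin of the control as well, but with a median of 0.277 (upper quartile 0.578), and 39 other cytokine receptor genes had a median of 0.243 (upper quartile 0.48). These values argue against a general response of either group as the whole cause of the control's rises, 9.47 for IL23R and 6.96 for IL12RB2. A drug-induced promoter at the locus that reads on downstream would spare the surroundings, and 1 other gene within 500 kb changed at least 2 times in every line, C1orf141, which overlaps IL23R on the opposite strand and had 29 counts without and 135 with induction, beside 33 and 10273 of IL23R, over the chromatin libraries of all lines. AL389925.1, which lies between the 2 receptor genes on their strand, had 0 and 76 counts in these. Counts had been made by strand, but the source of the few C1orf141 counts was not shown, and the threshold was set after its rise was seen, so an induced promoter, possibly of an inserted construct, stays open.

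Other splits of the libraries into groups of the same sizes were refitted. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each of the 11 contrasts between 2 groups 1 split called as many genes as the real one, the real one itself. The highest other was 0 genes in 10 of these contrasts (real counts of 10668, 10133, 8857 and 7492 for the cytoplasmic clone1, clone2 and control responses and the clone1 baseline, 10332, 9406, 11447, 7718 and 6345 for the 5 in chromatin, and 22472 for fractionation) and 244 for the cytoplasmic clone2 baseline (real count 6761). For the other contrasts 100 splits were drawn. These exchanged libraries within a line only, so they cannot address differences between cultures. The share as large was under 0.05 for the cytoplasmic net response (2 of 100 as large; real 5933, highest other 7229), the cytoplasmic response in both clones (2; 3121, 5042), the chromatin response in both clones (3; 708, 2397), the chromatin clone difference (4; 637, 9946) and the fraction difference (2; 3182, 4189). The share was 0.05 or more for the cytoplasmic clone difference (7; 405, 10989) and the chromatin net response (7; 2933, 6807). The number of splits was raised to 100 after the first 40 had been seen. In those 40, 3 were as large for the chromatin response in both clones and 2 for each of the other 4 results now under 0.05, shares of 0.05 or more. The 5 shares under 0.05 therefore rest on the later draws, and chance is not called excluded for any of them. Of the splits besides the real one that called as many genes, those that kept or reversed a whole line numbered 1 of 1, 1 of 1, 2 of 2, 3 of 3 and 1 of 1 in the order given, and 6 of 6 in each of the last 2. The highest counts were several times the real ones for the clone differences. The 10989 calls for the cytoplasmic clone difference came from a split that kept clone1 whole and reversed clone2, so their responses added up. The 7229 for the cytoplasmic net response came from a split that kept both clones whole and mixed the control. Such splits carry the induction responses, so their counts do not measure chance alone. Of the 32 splits that kept or reversed a line, 17 called no gene for the cytoplasmic net response.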

How the results depend on the processing

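Only the alternative restricted to genes without a same-strand overlapping gene of at least 20% of their own count was chosen after seeing the data. No named gene and no list that passed changed direction under the alternatives run. The larger side of the calls turned in the fraction difference, from 58.9% higher to 30.4% with RLE factors and 29.5% with DESeq2, in the chromatin clone difference, from 63.7% to 38.2% with library totals and 45.4% with DESeq2, and in the chromatin net response, from 47.1% to 80.1% with the technical libraries summed. It also turned under some alternatives where the sides were near even, as in the cytoplasmic control response, the chromatin responses and the baselines. The counts of called genes stayed within 1.5 times of those reported under RLE factors and a filter of a mean CPM of at least 1. The cytoplasmic clone difference was 194 genes with library totals alone, 816 with no filter beyond 1 count, 624 with DESeq2 and 79 with clone1 replicate 3 grouped as clone2, against 405. The chromatin clone difference was 1185 with no filter, 960 with DESeq2 and 45 with clone1 replicate 3 grouped as clone2, against 637. That grouping also gave 1808 genes in the chromatin net response and 397 in both clones, against 2933 and 708. With the technical libraries summed the net response had 1577 genes in the cytoplasm and 342 in chromatin, where fewer samples per line were compared. With an estimated correlation 0 lists passed in the cytoplasmic net response and 0 in chromatin, against 17 and 11, and with fry 2 passed in chromatin, ATF4 targets and cholesterol synthesis. In the cytoplasm fry passed 17 lists, 14 of them shared with camera, and lost translation factors (adjusted p = 0.137), ribosomal protein genes (0.342) and snoRNAs (0.215). The responses of the fractions had r = 0.344 over genes with a mean CPM of at least 1 in both, against 0.268. Apart from the summed libraries and the gene restriction, the cause was not tested.

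With the replicate block, the replicate number added to the model, the counts were 5652, 2967 and 296 for the cytoplasmic net response, both clones and clone difference, 3058, 728 and 651 in chromatin, and 3122 for the fraction difference, with 17 and 11 lists. Among genes without a same-strand overlapping gene of at least 20% of their own count, 4846 and 2506 were called in the cytoplasmic net response and in both clones. In chromatin these were 2643 and 648, with fewer genes tested.

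Leaving out 1 library at a time gave ranges of 9651 to 10938 genes for the cytoplasmic clone1 response, 9117 to 10468 for clone2, 7897 to 9010 for the control, 5092 to 5956 for the net response, 2771 to 3126 for both clones, and 6467 to 7645 and 5272 to 6889 for the baselines. In chromatin these were 8838 to 10812, 7923 to 9626, 10178 to 11933, 2052 to 4294, 503 to 1115, and 6305 to 8262 and 5046 to 6573. The fraction difference had 2724 to 3499 and fractionation 22056 to 22741. The clone difference ranged from 153 (without induced clone1 replicate 2) to 657 (without control replicate 2) in the cytoplasm and from 299 (without induced clone2 replicate 2) to 899 (without clone1 replicate 2) in chromatin, and the lowest and highest chromatin counts in both clones came without induced control replicate 2 and without clone2 replicate 3. Of the 216 results for named genes, 212 had the same outcome with DESeq2, 216 with RLE factors and 186 with clone1 replicate 3 grouped as clone2. With the technical libraries summed, which gave results for the net responses only, 56 had the same outcome, 49 lost the call and 1 gained it. With 1 library left out, the outcome was the same in 3892 refits, lost in 159 and gained in 17.

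Depth limited genes near the floor. IL23R without induction had 0 counts in the clone1 cytoplasm, and VLDLR-AS1 lay below 0.3 CPM there.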

Other observations

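The test on partial XRN1 loss and the lists of SR proteins, microRNA hosts, and hnRNP and CLK genes were chosen only after the results were seen. Genes of SR splicing factors, which carry conserved exons that trigger NMD, were higher in the cytoplasmic net response in 7 of 13, 1 of them, TRA2B, in both clones as well, with a median of 0.14 (limma camera adjusted p = 0.0131; adjusted p = 0.255 with an estimated correlation). Host genes of microRNAs were lower in 7 of 24, 5 of them in both clones, with a median of −0.09 (limma camera adjusted p = 0.0274; adjusted p = 0.255 with an estimated correlation). The pooled list of hnRNP and CLK genes, which also holds hnRNP pseudogenes matched by symbol, was higher in 9 and lower in 7 of 34, 6 and 7 of them in both clones (limma camera adjusted p = 0.563). Its families differed. CLK1, CLK4, CLK2 and CLK3 rose in both clones, with net changes of 1.01, 0.81, 0.44 and 0.29, as did HNRNPA1L2 and HNRNPLL. All of the lower members were hnRNP genes, so the pooled test does not describe the CLK genes alone. In chromatin none of the 3 lists passed limma camera, with adjusted p = 0.668, 0.668 and 0.463.

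Part of the RNAs that rose most in the induced clones were already higher in the clones before induction, in the cytoplasm. Over 216 genes that rose at least 2 times in both clones in the cytoplasm, the median baseline was 0.40 in clone1 and 0.44 in clone2 in the cytoplasm, against 0.01 and −0.03 in chromatin. The difference between fractions had medians of 0.43 (quartiles 0.17 and 0.65) and 0.49 (quartiles 0.18 and 0.74), and 47.7% and 47.2% of these genes were called higher before induction, against 19.9% and 17.3% of all genes. Called lower were 10 and 7 of the 216, and the rest did not pass. A candidate explanation is partial XRN1 loss before induction, through leaky TIR1 or a tag that lowers XRN1 activity. XRN1 mRNA was also lower in the cytoplasm of the clones. The gene was edited there and reads were aligned to the reference genome, so that count was not shown to track XRN1 protein or activity. Differences between the clones and the control that do not involve XRN1 stay open.

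Genes chosen by fractionation in the control line changed unequally in the cytoplasm. Of the 1938 genes most enriched in chromatin, 145 rose and 70 fell in both clones, while the next 3 groups of 1937 or 1938 held the most rises, 317, 340 and 328, against 42, 37 and 41 falls. Of the 1938 most cytoplasmic 35 rose and 293 fell, with a median net change of −0.077. The not induced control libraries enter both the ranking and the net change.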
